A study of Rattus norvegicus with 191 samples.

How the data were processed

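Gene expression was measured in hepatocytes taken by laser from frozen liver sections of rats of the Sprague-Dawley strain, either wild type (WT) or with the aryl hydrocarbon receptor knocked out (KO), after TCDD in corn oil by oral gavage. Per the labels' protocols, the small amounts of RNA were amplified to cDNA with a NuGen Ovation Pico kit, labelled with biotin and hybridised to Affymetrix arrays. Amplification from little RNA can add noise to single arrays, and the labels mark 5 arrays repeated from fresh RNA and 3 arrays scanned again. The deposited values are log2 expression values that the authors made with RMA and Partek, per the submitters' processing notes. Versions of these, and whether RMA was run over all arrays at once, are not given in the sources used here. Nothing was done to the values before testing. Over the 13438 genes tested, chosen as described below, they had a median of 5.74 and a maximum of 13.36. Arrays give no read depth, so the number of arrays limits the precision, and values near the top of the range can be compressed, which was not tested.

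The value table held 31139 probe sets on 191 arrays, and each column was matched to its sample by name. In the platform's annotation 1 gene symbol was given for 19068 probe sets, several for 573 and none for 11498. Of the first kind 18989 matched the rat gene table of the assembly GRCr8 by gene ID, which was used for names alone. Probe sets with several symbols were not named. For the 3986 genes with more than 1 probe set, the one with the highest mean over all arrays was taken, which left 13438 genes. The plan made before the data were examined spoke of transcript clusters, and the features turned out to be probe sets, to which the same test was applied.

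Groups, doses and animal numbers came from the labels, which call the samples biological replicates. The design text mentions 10 rats per dose and genotype, and the animals beyond the 8 with arrays were not analysed here. Several labels disagree with one another or with the values. The treatment text describes a short dosing of numbered animals, while the exposure label gives 28 days. The growth text calls the rats male, while Xist, transcribed from the inactive X chromosome, was at 10.50 or more on the arrays of all animals but 2, and Eif2s3y, a gene of the Y chromosome, was at most 2.77 on any array. Number 17 stands under both genotypes and was kept as 2 animals, whose arrays correlated at 0.984 in centrilobular and 0.9839 in periportal captures, against medians of 0.972 and 0.9743 for any 2 arrays of a zone. No 2 arrays held identical values, and the highest correlation between arrays was 0.9922.

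The first principal component of the deviations from group means held 28.8% of their variance in centrilobular and 32.3% in periportal arrays, and it separated animals by their number. Animals with numbers ending in 1 to 6 are called set A, and those ending in 7, 8, 9 or 0 set B. Of 60 set A arrays per zone 56 lay below the midpoint of that component, and 35 of 36 set B arrays in centrilobular and 35 of 35 in periportal captures lay above it. The labels do not say what the sets are. Each group held 5 arrays of set A and 3 of set B, apart from 2 of set B in the KO periportal group at 1000 ng/kg/day, so the sets are nearly balanced over the groups. Counts are therefore also given with the set as a block and within each set, choices made after this was seen.

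In each zone a limma model with a mean for each of the 12 groups of genotype and dose was fitted to the log2 values (lmFit and eBayes), so that all groups shared an estimate of the spread. Differences between the zones, and whether a response differed between them, were tested on the centrilobular minus periportal difference of each of the 95 animals with both arrays. The response by genotype was tested as the TCDD effect in WT minus that in KO animals, and any response in KO animals by an F test over the 5 dosed groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 13438 genes of a comparison. Adjusted p-values for genes are from limma throughout. In 10 of the 26 comparisons, 28 gene lists of liver pathways, zone markers and other cell types were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and 64 listed genes were not analysed.

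The comparisons, the lists, most of the other settings tried and the rule for naming genes were fixed before the data were examined. By that rule Ahr came first and then Cyp1a1. Each main comparison could name the 10 largest rises and the 10 largest falls among called genes. Each list could name up to 4 members, called ones with the largest change first and otherwise the one with the smallest p. Every measured member of the AHR gene battery was taken at all doses, and counts of 5 or fewer could name their genes. Xist, Eif2s3y and the genes that separate the sets fall outside the rule and were chosen after their values were seen, as were, for the animals described in the closing part, the arrays' values of sex-biased genes.

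The other settings fixed at that time were quantile normalization of the deposited values, a filter on dim genes, a trended and robust prior, array quality weights, a fit of the compared groups alone, every probe set, leaving out repeated or rescanned arrays, leaving out both animals numbered 17, the replicate number as a block, unpaired zones, and for lists an estimated correlation and a brighter background of 8424 genes. Settings added after the data were seen were the set as a block, each set alone, leaving out 9 animals that stood apart, and leaving out each array in turn where 5 or fewer genes were called. Whether replicate numbers pair samples was checked by correlating deviations from group means. In WT groups animals of equal number also belonged to the same set, so such correlations can come from the sets. Every pair of equal number exceeded 0.1 in 4 comparisons of WT animals with undosed ones: centrilobular at 3 (lowest 0.16) and 22 ng/kg/day (lowest 0.113), and periportal at 22 (lowest 0.178) and 100 ng/kg/day (lowest 0.129). The arrays of 1 animal correlated at a median of 0.378, above 0.1 in 89 of 95 animals.

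The fits were tested on simulated data before use. For TCDD at 1000 ng/kg/day in WT centrilobular captures, with 13438 genes, 46 of 67 genes changed 1.5-fold (68.7%), 63 of 67 changed 2-fold (94%) and 66 of 66 changed 4-fold were called, with 12 of 13238 unchanged genes. For the response by zone at that dose 40 of 67 (59.7%), 60 of 67 (89.6%) and 65 of 66 (98.5%) were called, with 7 unchanged genes. With no change simulated, 0 genes were called for TCDD in KO centrilobular captures and for the zone difference by genotype. The simulated genes were drawn independently of one another and without the animal sets. Their false calls therefore do not measure those on the real arrays. Each result was set against 100 splits of the same animals. Software was R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.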

Results

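Rat liver cells were cut out of stained frozen sections with a laser and their RNA was measured on expression arrays. Each animal gave a centrilobular sample, hepatocytes around the central vein, and a periportal sample, hepatocytes around the portal tracts. The animals were wild type (WT) or lacked the aryl hydrocarbon receptor (KO), the transcription factor that binds dioxins. They had been given TCDD, a long-lived dioxin, at 0, 3, 22, 100, 300 or 1000 ng/kg/day, with an exposure of 28 days in the labels. The 24 groups of genotype, zone and dose held 8 arrays each, except the KO periportal group at 1000 ng/kg/day with 7. In all there were 191 arrays of 96 animals, and 95 animals had both zones. Values are log2 array signals, a change is a difference of log2 values with its standard error (SE), and 13438 genes were tested in every comparison. The number of arrays, not read depth, limits the precision.

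Ahr, the gene knocked out, had a mean of 8.85 ± 0.30 (SD, n = 8) in centrilobular captures of undosed WT animals and 7.89 ± 0.64 (SD, n = 8) in those of undosed KO animals. In periportal captures the undosed means were 6.80 ± 0.42 in WT and 5.80 ± 0.71 in KO animals (SD, n = 8 each). Over the 6 doses the KO group means lay between 7.58 and 7.89 in centrilobular and between 5.58 and 5.87 in periportal captures, so the KO arrays kept an Ahr signal. Whether the probes lie inside the deleted part is not given in the sources used here, and Ahr therefore checked the genotype labels only in part. Cyp1a1, a cytochrome P450 induced through the receptor, checked them further. On every array of a dosed WT animal Cyp1a1 lay above every KO array of the same zone and dose, with the smallest gap in periportal captures at 3 ng/kg/day, where the lowest WT value was 5.10 and the highest KO value 3.65.

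Which genes differed between the zones without TCDD was asked within undosed animals. In WT animals Slc1a2, a glutamate transporter of the hepatocytes next to the central vein, was 4.82 ± 0.33 (SE, n = 8) higher in centrilobular captures. Car2, a carbonic anhydrase, was 4.09 ± 0.33 higher, Fmo1, a flavin monooxygenase, 3.79 ± 0.43 higher, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, 3.54 ± 0.41 higher. On the periportal side Aldh1b1, a mitochondrial aldehyde dehydrogenase, differed by -4.16 ± 0.40, Hal, which breaks down histidine, by -3.75 ± 0.41, Gldc of the glycine cleavage system by -3.75 ± 0.33, and Gls2, the liver glutaminase, by -3.43 ± 0.35. In all, 2141 genes were called, 1054 higher in centrilobular and 1087 higher in periportal captures, and 240 of them differed at least 2-fold (limma, Benjamini-Hochberg adjusted p under 0.05). Ahr itself was 2.05 ± 0.16 higher in centrilobular captures (adjusted p = 4.5e-19). With animal set as a block 2156 genes were called, and 1159 and 1397 in the sets alone; what the sets are is given with the processing.

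The gene lists fixed beforehand followed the zones. All 17 measured pericentral hepatocyte markers were higher in centrilobular captures (17 adjusted over the list alone), among them Axin2, a target of Wnt signalling, by 2.88 ± 0.23. Of 20 periportal hepatocyte markers 17 were lower and 1 higher (18 adjusted over the list alone). Of 13 gluconeogenesis genes 10 were lower in centrilobular captures, such as Gpt, an alanine aminotransferase, by -2.58 ± 0.22, and Pck1, which makes phosphoenolpyruvate, by -1.56 ± 0.33 (11 adjusted over the list alone). Acute phase genes, secreted in inflammation, were lower for 13 of 19, including A2m by -2.52 ± 0.30 and the iron hormone gene Hamp by -1.70 ± 0.22, with 1 higher (15 adjusted over the list alone). These 4 lists passed camera with its preset and with an estimated correlation. Cholesterol synthesis genes were higher for 11 of 19, such as Msmo1, a sterol oxidase, by 0.99 ± 0.15 (16 adjusted over the list alone), and fatty acid synthesis genes for 8 of 16, led by Scd, a fatty acid desaturase, by 2.60 ± 0.25, with 2 lower (12 adjusted over the list alone). Both lists passed camera with its preset correlation and with the brighter background, but not with an estimated correlation (adjusted p = 0.0874 and adjusted p = 0.102). Markers of other cells differed too. Of 9 cholangiocyte markers 5 were lower in centrilobular captures, such as Krt19, a keratin of bile ducts, by -1.40 ± 0.24, and none higher (camera adjusted p = 0.00164, adjusted p = 0.0922 with an estimated correlation). Of 9 endothelial markers 4 were higher, such as Lyve1 of sinusoids by 0.59 ± 0.10 (camera adjusted p = 0.0178, adjusted p = 0.0922 with an estimated correlation).

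In undosed KO animals 1747 genes differed between the zones, 861 higher in centrilobular and 886 higher in periportal captures (1777 with set as a block, 1005 and 686 in the sets alone). Ahr was 2.09 ± 0.16 higher in centrilobular captures (SE, n = 8), close to its difference in WT animals (KO minus WT 0.04 ± 0.23, adjusted p = 0.994). Of the genes higher in centrilobular captures 563 were called in both genotypes, against 67.5 for independent lists, and of those higher in periportal captures 626, against 71.7. Tested directly, 1 gene had a zone difference that depended on genotype: Cyp1a2, a cytochrome P450 of drug metabolism that the receptor also induces. It was 1.03 ± 0.29 higher in centrilobular captures of WT animals and 4.44 ± 0.29 higher in those of KO animals, a difference of 3.40 ± 0.40 (limma adjusted p = 8.44e-09, 722 genes had an unadjusted p under 0.05). The difference was 3.86 ± 0.37 in set A alone, where 1 gene was called. In set B alone, with fewer animals, it was 2.63 ± 0.72, and 0 genes passed limma with 949 at an unadjusted p under 0.05. The Cyp1a2 mean in WT centrilobular captures, 12.08, lay near the top of the array's range, and it reached 12.94 at 1000 ng/kg/day. Any compression there shrinks the WT zone difference and enlarges the 3.40, and its share was not measured.

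Undosed KO and WT animals differed mainly in Cyp1a2. In periportal captures its mean was 11.05 ± 0.35 in WT and 6.37 ± 1.38 in KO animals (SD, n = 8 each), a change of -4.68 ± 0.38 (adjusted p = 2.13e-16), and it was the 1 gene called there. In centrilobular captures Cyp1a2 was 12.08 ± 0.21 in WT and 10.81 ± 0.18 in KO animals (SD, n = 8 each), a change of -1.28 ± 0.12 (adjusted p = 9.19e-14). The other gene called there was Ahr, at -0.96 ± 0.20 (adjusted p = 0.0305), and that call was lost in 11 of 16 refits that each left out 1 array. In periportal captures Ahr differed by -1.0 ± 0.27 (adjusted p = 0.943). Of the 9 measured genes of the AHR gene battery, the known targets of the receptor, 1 fell in each zone, Cyp1a2 (2 adjusted over the list alone), and the list was lower by camera in both (adjusted p = 0.000748 centrilobular, 1.17e-06 periportal). The list medians were -0.1 centrilobular and -0.146 periportal, against means of -0.249 and -0.655 on which Cyp1a2 weighs heavily. Cholesterol synthesis genes were lower as a list in centrilobular captures (camera adjusted p = 4.68e-10, adjusted p = 0.144 with an estimated correlation) with 0 of 19 called by limma and 2 adjusted over the list alone. Pmvk, a kinase of that pathway, was at -0.60 ± 0.16 (unadjusted p = 0.000222, limma). Macrophage markers were lower as a list in the same captures (camera adjusted p = 0.000197, adjusted p = 0.179 with an estimated correlation), with 0 of 11 called, also adjusted over the list alone, and Cd163, a scavenger receptor of Kupffer cells, at -0.59 ± 0.23 (unadjusted p = 0.0111, limma).

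The dose series in WT animals showed at which doses each zone responded. In centrilobular captures Cyp1a1 rose from 4.23 ± 0.77 without TCDD to 11.04 ± 0.39 at 3 ng/kg/day (SD, n = 8 each), a change of 6.81 ± 0.28 (SE; adjusted p = 4.45e-37). In periportal captures it rose from 3.75 ± 0.66 to 6.69 ± 1.13 (SD, n = 8 each), a change of 2.94 ± 0.23 (adjusted p = 4.8e-17). The periportal change was 3.26 ± 0.28 in set A alone and 2.41 ± 0.44 in set B alone, where 0 genes passed limma, 458 had an unadjusted p under 0.05 and Cyp1a1 had an adjusted p of 0.0888. The rise at this dose differed between the zones by 3.87 ± 0.32 (adjusted p = 5.59e-16), with 3.46 ± 0.43 and 4.55 ± 0.47 within sets A and B. Centrilobular RNA amounting to a median of 5.34% of the periportal RNA would give the periportal Cyp1a1 signal at 3 ng/kg/day. The Slc1a2 signal of the same 8 animals gives a median share of 3.66%. RNA of centrilobular cells with little Slc1a2 would be missed, so that share is no upper bound. From 100 ng/kg/day on the zones had nearly the same level, with 12.44 ± 0.10 centrilobular and 12.27 ± 0.08 periportal at 100 and 12.53 ± 0.13 and 12.54 ± 0.04 at 1000 ng/kg/day (SD, n = 8 each). The highest value of any tested gene on any array was 13.36, so differences at this level may be compressed, which was not tested.

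Cyp1b1, another P450 under the receptor, rose to 9.93 ± 0.25 in centrilobular captures at 22 ng/kg/day, a change of 6.43 ± 0.11 (adjusted p = 1.27e-68), when the periportal mean was 4.87 ± 1.1 (SD, n = 8 each) with a change of 1.18 ± 0.20. The zone difference was 5.25 ± 0.21 at 22 ng/kg/day (adjusted p = 4.75e-38), 1.97 ± 0.21 at 100 (adjusted p = 1.67e-11), and 0.47 ± 0.21 at 1000 (adjusted p = 0.171). Aldh3a1, an aldehyde dehydrogenase, was at most 4.35 on every WT array up to 22 ng/kg/day. It rose at 100 in centrilobular captures by 3.69 ± 0.20, when the periportal difference was 0.32 ± 0.21 (adjusted p = 0.947). In periportal captures Aldh3a1 rose by 3.25 ± 0.21 at 300 and by 6.66 ± 0.21 at 1000 ng/kg/day. The zones differed by 3.37 ± 0.23 at 100, 3.54 ± 0.23 at 300 and 1.41 ± 0.23 at 1000 ng/kg/day. Undosed Aldh3a1 and Cyp1b1 lay in the dim part of the arrays, which limits the sizes of their rises and zone differences. The Aldh3a1 mean of 11.95 in centrilobular captures at 1000 ng/kg/day is near the top of the range, where any compression shrinks the 1.41. Nqo1, a quinone reductase, rose at 3 ng/kg/day in centrilobular captures by 0.89 ± 0.17 and in periportal ones at 100 ng/kg/day by 2.23 ± 0.24. Ahrr, which represses the receptor, was called in both zones at 100 ng/kg/day, with 2.08 ± 0.15 centrilobular and 1.28 ± 0.20 periportal. Nfe2l2, the regulator of the antioxidant response, rose from 22 ng/kg/day on in centrilobular (0.66 ± 0.12) and from 100 on in periportal captures (0.68 ± 0.13). Cyp1a2 rose at 22 ng/kg/day in centrilobular captures by 0.81 ± 0.12 and at 100 in periportal ones by 1.84 ± 0.38, to a mean of 12.89 in each, where changes may be compressed too. Xdh, xanthine dehydrogenase, rose at 1000 ng/kg/day alone, by 0.87 ± 0.14 in each zone. Cyp2s1 was called at no dose in either zone (0.04 ± 0.11 centrilobular, -0.21 ± 0.12 periportal at 1000 ng/kg/day). Ahr rose in periportal captures at 300 ng/kg/day by 1.21 ± 0.27 (adjusted p = 0.00194) and at 1000 by 1.62 ± 0.27, and in centrilobular captures at 1000 by 0.57 ± 0.20 (adjusted p = 0.0229). Its WT centrilobular arrays spanned 8.93 to 9.87 at 100 and 8.53 to 10.04 at 1000 ng/kg/day, so the level at 1000 was not clearly above that at 100.

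**Figure D1:**
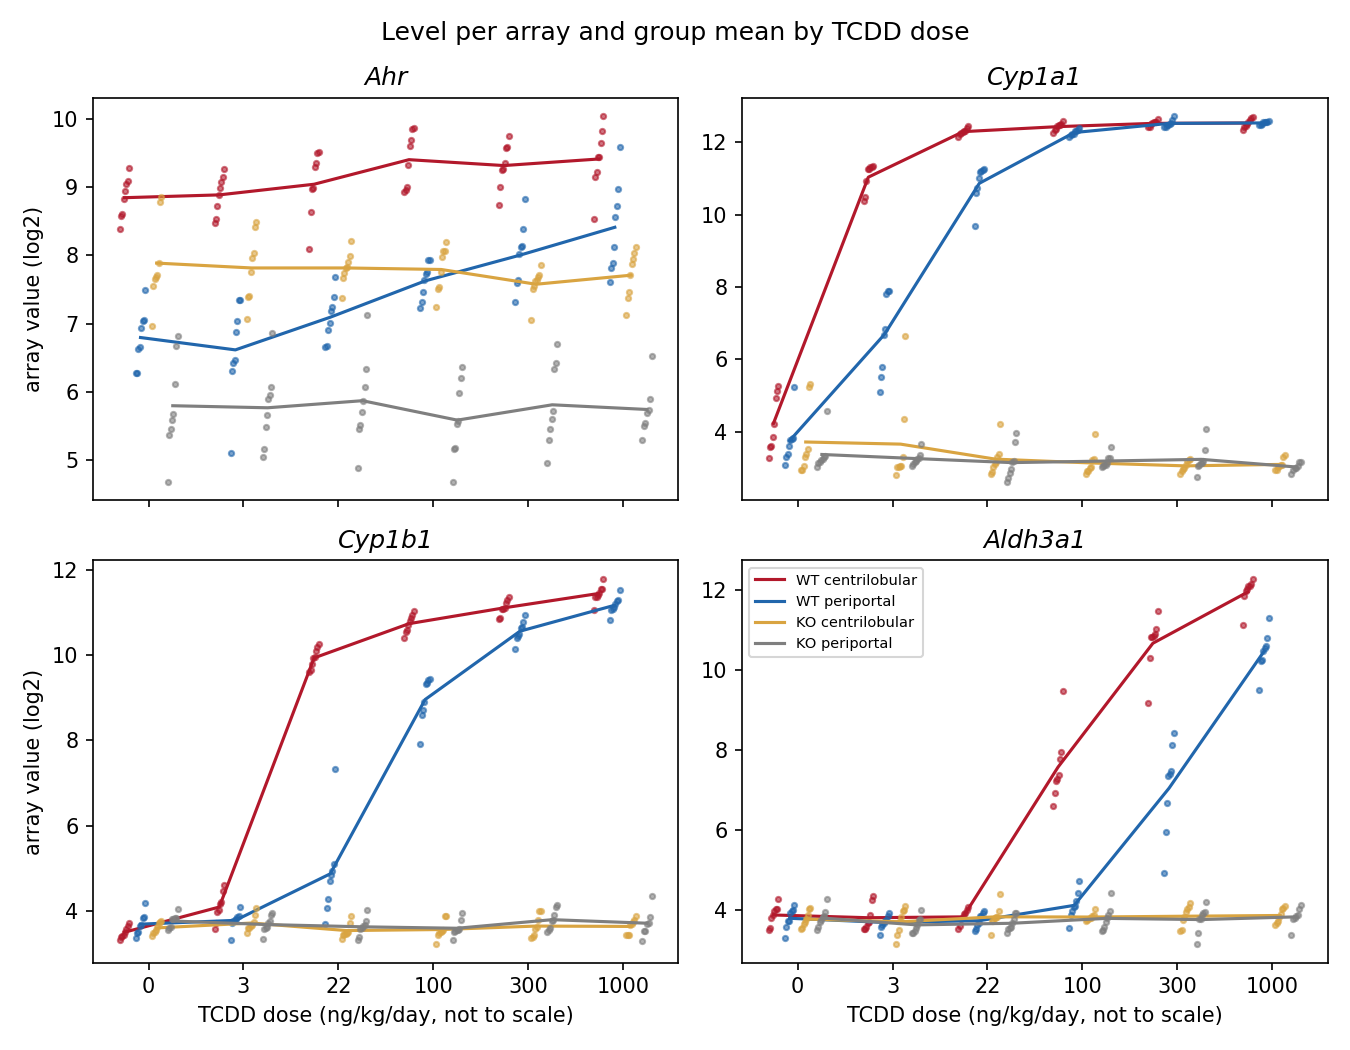
Array values (log2) of Ahr, Cyp1a1, Cyp1b1 and Aldh3a1 against TCDD dose (ng/kg/day, doses evenly spaced), with a point per array and a line through the group means for each genotype and zone. In WT animals Cyp1b1 reached a mean of 9.93 in centrilobular captures at 22 ng/kg/day and 8.96 in periportal captures at 100 ng/kg/day, while the KO lines stay level.

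The number of genes called against undosed WT animals grew with dose in both zones. In centrilobular captures it was 5 at 3 ng/kg/day, 70 at 22, 574 at 100, 1403 at 300 and 3381 at 1000 ng/kg/day. In periportal captures it was 1, 2, 56, 451 and 1587 at the same doses. The 5 genes at 3 ng/kg/day were Cyp1a1, Cyp1b1 (0.59 ± 0.11), Nqo1, Glrx, a glutaredoxin (0.78 ± 0.16), and Ccdc74a (0.39 ± 0.08). Leaving out 1 array at a time, Ccdc74a was lost in 6 of 16 refits and Glrx in 3. At 22 ng/kg/day the periportal genes were Cyp1a1 (7.12 ± 0.23) and Cyp1b1. A fit of the compared groups alone also called 2 genes there, of which 1 was shared with these. With set as a block the counts were 6, 110, 849, 1802 and 4158 centrilobular and 1, 2, 92, 684 and 2172 periportal. The replicate number was also used as a block, given here for the doses where samples of equal number all correlated above the bound given with the processing. The counts were then 6 and 126 centrilobular (3 and 22 ng/kg/day) and 2 and 100 periportal (22 and 100 ng/kg/day). In set A alone the counts were 2, 31, 361, 991 and 2570 centrilobular and 1, 1, 26, 327 and 1319 periportal. In set B alone they were 1, 17, 212, 767 and 2537 centrilobular and 0, 1, 18, 170 and 915 periportal.

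**Figure D2:**
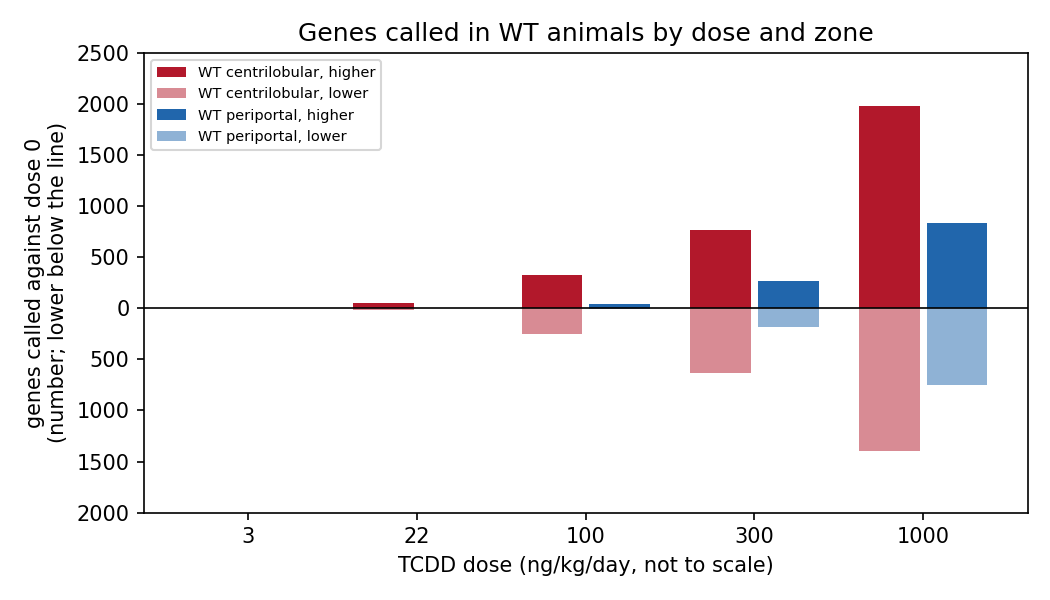
Genes called higher (above the line) or lower (below it) against undosed WT animals, by TCDD dose (ng/kg/day, evenly spaced) and zone. At 1000 ng/kg/day 1985 genes were higher and 1396 lower in centrilobular captures, and 834 higher and 753 lower in periportal captures.

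At 1000 ng/kg/day in centrilobular captures of WT animals Aldh3a1 was up by 8.07 ± 0.20 and Cyp1b1 by 7.94 ± 0.11 (SE, n = 8). Cyp1a1, with a signal near the top of the range, was up by at least 8.31 ± 0.28. Other large rises were those of Rbm24, an RNA-binding protein, by 7.82 ± 0.13, Scn4b, a sodium channel subunit, by 6.02 ± 0.15, Ahrr by 5.43 ± 0.15, Cox8b, a cytochrome oxidase subunit, by 5.42 ± 0.23, and Cyp2a3, a P450, by 5.36 ± 0.28. The undosed means of Aldh3a1, Cyp1b1, Rbm24, Scn4b and Cyp2a3 were 2.78 to 3.88, in the dim part of the arrays, so their rises are lower bounds too. The largest falls were those of the P450 gene Cyp3a9, at -6.70 ± 0.29, A1bg, a plasma glycoprotein, at -6.54 ± 0.84, and Car3, a carbonic anhydrase, at -5.84 ± 0.37. Genes of amino acid breakdown were among them, with Aass of the lysine pathway at -5.35 ± 0.26 and Prodh of the proline pathway at -4.59 ± 0.19, and so was Cd36, which takes up fatty acids, at -4.19 ± 0.18. Of the 3381 genes called, 1985 were higher and 1396 lower, and 748 changed at least 2-fold. Of the AHR gene battery 8 of 9 rose (8 adjusted over the list alone).

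Zone markers fell in these captures. Of 17 pericentral hepatocyte markers 9 fell and none rose (9 adjusted over the list alone), such as Slc13a3, a dicarboxylate transporter, at -2.92 ± 0.14, Cyp7a1 at -2.71 ± 0.45 and Slc1a2 at -2.57 ± 0.22. Of 20 periportal hepatocyte markers 10 fell and 4 rose (15 adjusted over the list alone), with the steroid dehydrogenase Hsd17b6 at -3.70 ± 0.39 and the lipid droplet gene Hsd17b13 at 2.21 ± 0.32 (camera adjusted p = 0.000327, adjusted p = 0.263 with an estimated correlation). Urea cycle genes fell for 6 of 8 (6 adjusted over the list alone), such as the mitochondrial carrier Slc25a13 at -1.93 ± 0.10 and Otc at -1.57 ± 0.18. Of 13 gluconeogenesis genes 6 fell and 3 rose (11 adjusted over the list alone; camera adjusted p = 0.00147, adjusted p = 0.231 with an estimated correlation). Of 11 glycolysis genes 6 fell, with the glucokinase regulator Gckr at -1.26 ± 0.13, and 2 rose (8 adjusted over the list alone).

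Lipid genes fell as groups. Cholesterol synthesis genes fell for 16 of 19 (17 adjusted over the list alone; camera adjusted p = 9.87e-16), with the sterol reductases Tm7sf2 at -2.21 ± 0.18 and Dhcr7 at -1.93 ± 0.21 and the isomerase Idi1 at -2.0 ± 0.26. Of 21 genes of fatty acid oxidation and PPARA targets 14 fell and 2 rose (16 adjusted over the list alone; camera adjusted p = 1.17e-14), with Ehhadh of peroxisomal oxidation at -3.0 ± 0.13 and Angptl4, an inhibitor of lipoprotein lipase, at -2.96 ± 0.21. Fatty acid synthesis genes fell for 11 of 16 and rose for 1 (12 adjusted over the list alone), such as the desaturase Fads2 at -1.82 ± 0.29 and Acly, which makes cytosolic acetyl-CoA, at -1.47 ± 0.23 (camera adjusted p = 1.3e-06, adjusted p = 0.138 with an estimated correlation). Of 16 genes of bile acid synthesis and transport 10 fell and none rose (11 adjusted over the list alone), with the uptake transporter Slc10a1 at -3.36 ± 0.22 and the bile acid receptor Nr1h4 at -1.81 ± 0.15.

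**Figure D3:**
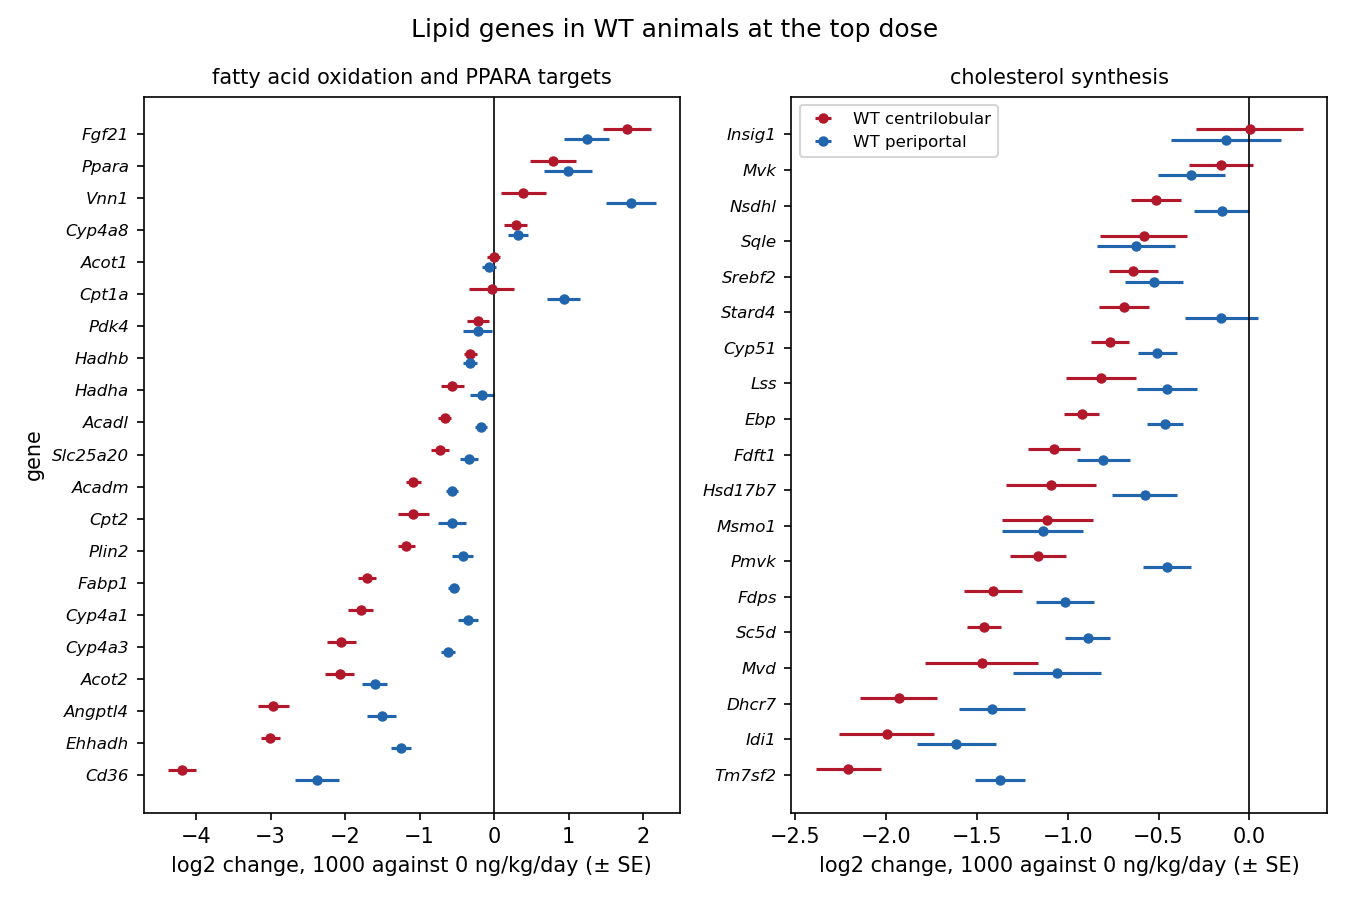
Change (log2, 1000 against 0 ng/kg/day, with SE bars) of each measured gene of fatty acid oxidation and PPARA targets and of cholesterol synthesis in the zones of WT animals, n = 8 per group. Cd36 fell by 4.19 in centrilobular captures and fell by 2.38 in periportal captures, the largest fall of the fatty acid list in each.

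Stress, inflammation and amino acid genes went both ways in the same captures. Asns, asparagine synthetase, rose by 3.51 ± 0.28, the stress factor Atf3 by 2.26 ± 0.47 and Trib3 by 2.01 ± 0.21. Of their list, the unfolded protein response, 8 of 18 rose and 3 fell (11 adjusted over the list alone; camera adjusted p = 0.0775, and the list median is below 0 while its mean is above). Phgdh, the entry step of serine synthesis, rose by 1.93 ± 0.18, while Cbs, of the transsulfuration pathway, changed by -2.84 ± 0.19. Of 14 genes of serine, one-carbon and amino acid metabolism 4 rose and 6 fell (11 adjusted over the list alone; camera adjusted p = 0.0126, adjusted p = 0.203 with an estimated correlation). NRF2 targets rose for 10 of 19 and fell for 4 (15 adjusted over the list alone; camera adjusted p = 0.0531), led by the cystine transporter Slc7a11 at 2.26 ± 0.20. Acute phase genes rose for 6 of 19 and fell for 3 (12 adjusted over the list alone), led by Lcn2, a lipocalin, at 4.27 ± 0.42. Of 11 CAR and PXR targets 3 rose and 5 fell (9 adjusted over the list alone; median 0.06, mean -0.60), with Cyp3a2 at 3.10 ± 0.59 and Alas1, the rate-limiting enzyme of heme synthesis, at -2.22 ± 0.20. Heme and iron genes rose for 3 of 15 and fell for 8 (13 adjusted over the list alone). Retinoid genes rose for 3 of 14 and fell for 4 (7 adjusted over the list alone). Growth hormone and sex-biased genes rose for 3 of 18 and fell for 6 (10 adjusted over the list alone), such as the prolactin receptor Prlr at -3.10 ± 0.39 and the growth hormone receptor Ghr at -1.63 ± 0.11. Clock genes rose for 3 of 16 and fell for 3, p53 targets rose for 1 of 10 and fell for 2, and cell cycle genes fell for 1 of 24 (6, 3 and 1 adjusted over the list alone).

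Some markers of other cells moved in these centrilobular captures as well. Stellate cell and fibroblast markers rose for 8 of 13 and fell for 3 (12 adjusted over the list alone), with the collagen genes Col1a1 at 2.57 ± 0.34 and Col1a2 at 1.71 ± 0.17 (camera adjusted p = 0.00788, adjusted p = 0.196 with an estimated correlation). Cholangiocyte markers rose for 3 of 9, such as the adhesion gene Epcam at 1.64 ± 0.19, endothelial markers for 2 of 9, lymphocyte markers for 3 of 8 and neutrophil markers for 2 of 6 (3, 3, 3 and 2 adjusted over the list alone). None of these lists passed camera (adjusted p = 0.173, 0.304, 0.304 and 0.61), and 3381 of all 13438 genes were called in this comparison. Macrophage markers rose for 1 of 11 and fell for 2 (3 adjusted over the list alone; camera adjusted p = 0.365), with Adgre1, a Kupffer cell surface receptor, at -0.94 ± 0.20. Erythroid markers were called for 0 of 3, with Hba-a3, a globin gene, at -0.38 ± 0.16 (unadjusted p = 0.0179, limma). With set as a block all 15 lists that passed camera here passed again in the same direction, and 14 and 13 of them within the sets.

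In periportal captures of WT animals at 1000 ng/kg/day Cyp1a1 rose by at least 8.79 ± 0.23, Rbm24 by 7.53 ± 0.14, Cyp1b1 by 7.47 ± 0.20, Cox8b by 6.51 ± 0.21 and Scn4b by 5.76 ± 0.20 (SE, n = 8). Undosed Cyp1b1 lay at 3.36 to 4.19 in these captures, in the dim part of the arrays, so its rise is a lower bound as well. Defb1, an antimicrobial peptide, rose by 4.69 ± 0.13 and Gstm3, a glutathione transferase, by 3.75 ± 0.24. The largest falls were those of A1bg at -5.52 ± 0.75, Car3 at -4.65 ± 0.42 and Serpina7, the thyroxine-binding globulin, at -4.31 ± 0.28. Of 1587 genes called 834 were higher and 753 lower, and 340 changed at least 2-fold. The AHR gene battery rose for 8 of 9 (8 adjusted over the list alone). Cholesterol synthesis genes fell for 14 of 19 (15 adjusted over the list alone), with Idi1 at -1.61 ± 0.22. Fatty acid oxidation genes fell for 10 of 21 and rose for 4 (18 adjusted over the list alone), with Cd36 at -2.38 ± 0.30 and the pantetheinase Vnn1 at 1.83 ± 0.33. Of 20 periportal hepatocyte markers 10 fell and 2 rose (12 adjusted over the list alone), with Hal at -2.34 ± 0.21 and Gls2 at -1.60 ± 0.13. Of 17 pericentral markers 3 rose and 3 fell (6 adjusted over the list alone; camera adjusted p = 0.889). Asns rose by 2.99 ± 0.27 and Trib3 by 2.78 ± 0.17. Of the unfolded protein response list 8 of 18 rose and 1 fell (11 adjusted over the list alone; camera adjusted p = 0.00576, adjusted p = 0.207 with an estimated correlation). The list mean was 0.43 but its median -0.06, and the call rested on set B (median 0.29, adjusted p = 5.45e-05), with a median of -0.22 in set A (adjusted p = 0.508). Stellate cell markers rose for 4 of 13 (5 adjusted over the list alone), with Col1a1 at 1.77 ± 0.37 (camera adjusted p = 0.0061, adjusted p = 0.199 with an estimated correlation). Macrophage markers fell for 3 of 11 (4 adjusted over the list alone), with Adgre1 at -1.24 ± 0.24 (camera adjusted p = 0.00361, adjusted p = 0.251 with an estimated correlation). All 14 lists that passed camera passed again with set as a block, and 12 and 11 within the sets.

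In KO animals 0 genes passed limma at 1000 ng/kg/day in either zone, with 488 at an unadjusted p under 0.05 in centrilobular and 395 in periportal captures. A test over the 5 dosed groups also called 0 genes in each zone, with 357 and 317 at an unadjusted p under 0.05. Cyp1a1 was at 3.09 ± 0.16 in centrilobular captures of KO animals at 1000 ng/kg/day (SD, n = 8) against 3.71 ± 0.99 in undosed ones, a change of -0.62 ± 0.28 (adjusted p = 1). Of the AHR gene battery 0 of 9 were called in each zone, with Cyp1b1 at 0.04 ± 0.11 centrilobular and -0.05 ± 0.21 periportal and Nqo1 at 0.06 ± 0.17 and 0.29 ± 0.25. Lists passed camera with its preset correlation alone: the unfolded protein response was lower in centrilobular captures (adjusted p = 0.000157, adjusted p = 0.173 with an estimated correlation) and in periportal ones (adjusted p = 0.000401, adjusted p = 0.489 with an estimated correlation). Fatty acid synthesis was lower in centrilobular ones (adjusted p = 0.00311, adjusted p = 0.816 with an estimated correlation), with medians of opposite sign in the sets (-0.335 in set A and 0.109 in set B). So were cell cycle genes (adjusted p = 0.0228, adjusted p = 0.603 with an estimated correlation) and stellate cell markers (adjusted p = 0.0157, adjusted p = 0.603 with an estimated correlation). Fatty acid oxidation genes were higher in periportal captures (adjusted p = 0.0425, adjusted p = 0.864 with an estimated correlation), a call that was lost with set as a block (adjusted p = 0.188). No member of these lists was called.

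The TCDD effect at 1000 ng/kg/day was tested directly between the genotypes. In centrilobular captures 2022 genes changed differently in WT and KO animals, 1140 more upwards and 882 more downwards in WT. The difference was at least 8.93 ± 0.39 for Cyp1a1, 7.88 ± 0.19 for Rbm24 and 5.26 ± 0.39 for Cyp2a3 (SE, n = 8 per group), and -6.96 ± 0.41 for Cyp3a9 and -5.66 ± 0.53 for Car3. Dim undosed signals limit the sizes for Rbm24 and Cyp2a3. In periportal captures 786 genes did so, 407 upwards and 379 downwards, with at least 9.14 ± 0.34 for Cyp1a1, 4.65 ± 0.19 for Defb1, -6.14 ± 1.08 for A1bg and -4.48 ± 0.41 for Serpina7. The A1bg value includes KO animals with low A1bg at either dose, undosed replicates 4 (7.05) and 7 (3.99) and replicate 2 at 1000 ng/kg/day (4.71). It was -5.3 ± 1.3 in set A alone and -7.6 ± 1.8 in set B alone. Cholesterol synthesis genes moved more downwards in WT animals for 15 of 19 in centrilobular and 7 of 19 in periportal captures (15 and 11 adjusted over the list alone), the latter with camera adjusted p = 2.03e-10 and adjusted p = 0.091 with an estimated correlation. Fatty acid oxidation genes did so for 12 of 21 (1 more upwards) and 8 of 21 (14 and 16 adjusted over the list alone), such as Ehhadh at -3.01 ± 0.18 and -1.12 ± 0.19. Markers of other cells differed beside them: stellate cell markers moved more upwards in WT animals for 7 and 3 of 13 (9 and 3 adjusted over the list alone; camera adjusted p = 0.000932 and 0.00216, adjusted p = 0.0827 and 0.139 with an estimated correlation). Macrophage markers moved more downwards for 1 of 11 in periportal captures (4 adjusted over the list alone; camera adjusted p = 0.00179, adjusted p = 0.267 with an estimated correlation). Of 13 lists that passed camera in periportal captures 11 passed again with set as a block, without those of the urea cycle (adjusted p = 0.0502) and gluconeogenesis (adjusted p = 0.1). With set as a block 2609 centrilobular and 1106 periportal genes were called, with 1493 and 570 in set A and 1169 and 338 in set B.

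Whether the zones of WT animals responded differently was tested on the difference between the arrays of each animal. At 1000 ng/kg/day 1160 genes did, 568 more upwards and 592 more downwards in centrilobular captures. Cyp2a3 rose more in centrilobular captures by 3.12 ± 0.24 (SE, n = 8 per group), Il1rn, the interleukin-1 receptor antagonist, by 2.21 ± 0.27, and the transcription factor Sox17 by 2.07 ± 0.26. On the other side stood Sult1c3 at -5.38 ± 0.43 and Sult2a2 at -3.55 ± 0.47, sulfotransferases, Defb1 at -3.53 ± 0.21 and the chemokine Cxcl13 at -3.47 ± 0.54. Fatty acid oxidation genes fell more, or rose less, in centrilobular captures for 15 of 21 (15 adjusted over the list alone; camera adjusted p = 8.36e-22), such as Cd36 by -1.81 ± 0.22 and Ehhadh by -1.76 ± 0.14. Urea cycle genes did so for 6 of 8 (7 adjusted over the list alone), such as Ass1 by -1.39 ± 0.29. Bile acid genes did for 8 of 16 with 1 the other way (10 adjusted over the list alone), such as Slc10a1 by -2.49 ± 0.18, and pericentral hepatocyte markers did for 9 of 17 (11 adjusted over the list alone), such as Aldh1a1, a retinal dehydrogenase, by -1.97 ± 0.14. Cholesterol synthesis genes fell more for 7 of 19 (10 adjusted over the list alone; camera adjusted p = 9.55e-07, adjusted p = 0.117 with an estimated correlation). Ahr, higher in centrilobular captures without TCDD, rose less there, by -1.05 ± 0.23 (adjusted p = 0.000405). At 3, 22, 100 and 300 ng/kg/day 1, 43, 257 and 454 genes responded differently between the zones. With set as a block the counts were 43, 269 and 474 from 22 to 300 ng/kg/day and 1180 at 1000 ng/kg/day. The sets alone gave 12, 72, 140 and 526 (set A) and 14, 32, 92 and 681 (set B) from 22 ng/kg/day on.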

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

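The tests of the animal sets for the number of genes called, and of sex and labels for the KO animals with high Cyp2c13, were chosen after those results were seen, as were the sets themselves.

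Among 80 groups of arrays whose values the text gives, 12 held an array far from the others, by the gap to its neighbour over the range of the group; chance gives about 1 in 20 groups. Ahr was at 5.11 in WT periportal replicate 3 at 3 ng/kg/day, with the others from 6.31 to 7.35, and at 7.05 in KO centrilobular replicate 3 at 300 ng/kg/day (others 7.51 to 7.86). In WT periportal captures Cyp1a1 was at 5.24 in undosed replicate 6 (others 3.07 to 3.83) and at 9.68 in replicate 8 at 22 ng/kg/day (others 10.61 to 11.26). In KO centrilobular captures it was at 6.64 in replicate 5 at 3 ng/kg/day (others 2.80 to 4.35), at 4.22 in replicate 5 at 22 (others 2.82 to 3.39) and at 3.93 in replicate 3 at 100 (others 2.84 to 3.23). In KO periportal captures it was at 4.57 in undosed replicate 6 (others 3.01 to 3.32) and at 3.57 in replicate 2 at 100 ng/kg/day (others 3.02 to 3.28). Cyp1b1 was at 7.33 in WT periportal replicate 7 at 22 ng/kg/day (others 3.70 to 5.10). Aldh3a1 was at 9.47 in WT centrilobular replicate 1 at 100 ng/kg/day (others 6.61 to 7.96) and at 11.12 in replicate 8 at 1000 ng/kg/day (others 11.84 to 12.28).

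Responses that differed between groups by the test of the difference itself were counted for the zone difference by genotype (1 gene), for TCDD at 1000 ng/kg/day by genotype (2022 centrilobular and 786 periportal genes) and for TCDD by zone in WT animals (1, 43, 257, 454 and 1160 genes from 3 to 1000 ng/kg/day). The zone difference of Cyp1a2 without TCDD was 3.40 larger in KO animals, a value that any compression of the high WT centrilobular signal (mean 12.08) enlarges. By genotype the centrilobular response, as WT minus KO, was at least 8.93 for Cyp1a1, whose dosed WT signal lay near the top of the range. It was 7.88 for Rbm24 and 5.26 for Cyp2a3, both limited by dim undosed signals, and -3.01 for Ehhadh, -5.66 for Car3 and -6.96 for Cyp3a9. In periportal captures it was at least 9.14 for Cyp1a1, 4.65 for Defb1, -1.12 for Ehhadh, -4.48 for Serpina7 and -6.14 for A1bg. The A1bg value includes KO animals with high Cyp2c13 and low A1bg, described below. By zone, as centrilobular minus periportal, the response was 3.87 for Cyp1a1 at 3 ng/kg/day, 5.25 for Cyp1b1 at 22, 1.97 for Cyp1b1 and 3.37 for Aldh3a1 at 100, and 3.54 for Aldh3a1 at 300 ng/kg/day, sizes limited by dim signals without TCDD. At 1000 ng/kg/day it was above 0 for Cyp2a3 (3.12), Il1rn (2.21), Sox17 (2.07), Aldh3a1 (1.41), Phgdh (1.26), Cyp3a2 (1.15), Csf1r (0.95) and Cd2 (0.54). It was below 0 for Sult1c3 (-5.38), Sult2a2 (-3.55), Defb1 (-3.53), Cxcl13 (-3.47), Slc10a1 (-2.49), G6pc1 (-2.08), Aldh1a1 (-1.97), Cbs (-1.96), Cd36 (-1.81), Ehhadh (-1.76), Ass1 (-1.39), Ugt2b1 (-1.39), Ahr (-1.05), Fads1 (-1.04) and Gckr (-0.94).

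Cyp1a1 rose more in centrilobular than in periportal captures at 3 ng/kg/day. A difference between the animal sets is argued against, since the zones differed by 3.46 ± 0.43 in set A (limma adjusted p = 1.54e-06) and by 4.55 ± 0.47 in set B (limma adjusted p = 1.75e-06). For the periportal rise itself, the test could not tell centrilobular cells in the periportal captures from a response of the periportal cells. Cyp1a1 needs a share of 0.811% to 10.8% (median 5.34%). Slc1a2 gives a share of 1.63% to 9.92% (median 3.66%), with all its periportal signal counted as centrilobular. That is no upper bound, since RNA of centrilobular cells farther from the central vein, with little Slc1a2, would be missed. The needed share was higher in 5 of 8 animals (exact two-sided permutation p = 0.805), and a lack of difference over 8 animals does not show the source. Both stay open, as hypotheses.

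More genes were called at 1000 ng/kg/day in centrilobular than in periportal captures of WT animals, 3381 against 1587. The animal sets do not account for it, since 2570 against 1319 genes were called in set A and 2537 against 915 in set B, a smallest excess of 1251. A larger spread between periportal arrays was not decided by the median ratio of residual SDs, 1.02, which lay between the bounds set for the test. The median SDs were nearly equal, 0.279 periportal and 0.276 centrilobular, so any difference in the median spread was small. For larger effects in centrilobular cells the sizes of change were compared. Over the 3733 genes called in either zone the absolute change was larger there by a median of 0.26. Of these genes 3381 were chosen by their centrilobular call, which favours that sign. Over the genes called in periportal captures, a choice that favours the other sign, the change was still larger in centrilobular ones by 0.09, for 930 of 1587. Of 1235 genes called in both zones 1225 changed in the same direction, and the larger effect remains a hypothesis.

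Of 48 KO animals 7 had Cyp2c13, a P450 of male rat liver, at 8.86 to 12.11, against at most 7.44 on the other KO arrays and at most 6.13 on WT arrays of 48 animals. Male animals are argued against by Xist, at 11.22 or more on all their arrays. For the 5 of them dosed with 100 ng/kg/day or more, WT animals under a KO label are argued against by Cyp1a1. It was at most 3.93 there, against at least 12.14 in WT animals at these doses. The undosed ones, replicates 4 and 7, could not be tested this way. Ahr in replicate 4 (8.85 centrilobular, 6.82 periportal) lay within the undosed WT ranges (8.39 to 9.28 and 6.27 to 7.49), and in replicate 7 (7.89 and 5.36) below them. The sets held 3 of 30 and 4 of 18 KO animals of this kind (Fisher's exact test, two-sided p = 0.4), so such animals were not limited to a set. With the threshold on Cyp2c13 set after its values were seen, 7 of 48 KO and 0 of 48 WT animals (Fisher's exact test, two-sided p = 0.0124, which that choice makes too small) leave chance and a link with the genotype open, and hormones, age and litter were not tested.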

How the results depend on the processing

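The set as a block, each set alone, the fit without 9 animals and the leave-one-out fits were chosen after the data were seen, and the other alternatives were planned. Over 2028 alternative values of 171 pairs of a named gene and a comparison 1980 were counted as the same, 44 lost the call and 4 gained one. Among genes called in the main fit 0 reversed direction. A change of direction in a gene not called there was counted as the same. Quantile normalization, the filter on dim genes, and the trended and robust prior moved no count of genes by more than 1.5 times. With every probe set tested, a larger number of features, 3588 (zone, WT) and 2846 (zone, KO) were called, 1 for genotype in centrilobular captures, and 108, 885, 2339 and 5850 for WT centrilobular captures from 22 to 1000 ng/kg/day. The same setting gave 2579 for WT periportal captures at 1000 ng/kg/day, 3229 and 1193 for the response by genotype (centrilobular, periportal) and 1758 for the response by zone at 1000 ng/kg/day. With array quality weights WT periportal captures gave 87 genes at 100 and 728 at 300 ng/kg/day, and the cause was not tested. With only the compared groups in the fit, and so fewer arrays, 1 gene was called for genotype (centrilobular), 2 and 44 for WT centrilobular captures at 3 and 22 ng/kg/day, and 20 for the response by zone at 22 ng/kg/day. Without repeated or rescanned arrays the counts were 1 for genotype (centrilobular), 3 for WT centrilobular and 2 for WT periportal captures at 3 ng/kg/day, and without the animals numbered 17 genotype (centrilobular) gave 1.

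With the replicate number as a block WT centrilobular captures gave 126 genes at 22 and 912 at 100 ng/kg/day, and periportal ones 100 at 100 and 715 at 300 ng/kg/day; the other counts stayed within 1.5 times. Every pair of equal number exceeded a correlation of 0.1 for the counts of 126 and 100, but not for those of 912 and 715. In none did every sample correlate best with its own number (at most 5 of 8 pairs). Equal numbers in WT groups also share the set, so the correlations do not show a pairing beyond the sets. Without the pairing of zones within animals, no replicate block, the zones differed in 1161 (WT) and 881 (KO) genes, and 3, 26, 102 and 472 genes responded by zone from 22 to 1000 ng/kg/day. With the set as a block 110 genes were called for WT centrilobular captures at 22, and 92 and 684 for periportal ones at 100 and 300 ng/kg/day. The sets alone hold fewer animals. Set A gave 1159 (zone, WT), 1005 (zone, KO), 1 (genotype, centrilobular), 2, 31 and 361 (WT centrilobular, 3 to 100 ng/kg/day), 1 and 26 (WT periportal, 22 and 100), 1 (KO centrilobular at 1000, with 0 in all animals) and 12, 72, 140 and 526 (by zone, 22 to 1000 ng/kg/day). Set B gave 1397 (zone, WT), 686 (zone, KO), 0 (zone by genotype, limma, 949 at an unadjusted p under 0.05, with Cyp1a2 at 2.63 ± 0.72), 1 (genotype, centrilobular), 1, 17, 212 and 767 (WT centrilobular, 3 to 300 ng/kg/day) and 0, 1, 18, 170 and 915 (WT periportal, 3 to 1000, with 458 at an unadjusted p under 0.05 at 3). It also gave 1169 and 338 for the response by genotype and 14, 32, 92 and 681 by zone from 22 to 1000 ng/kg/day.

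With an estimated correlation camera called 6 lists for the zones in WT animals (13 with the preset), 1 of 8 and 1 of 6 for genotype (centrilobular, periportal), 7 of 14 for WT periportal captures, 0 of 4 and 0 of 2 in KO animals, 7 of 17 and 4 of 13 for the response by genotype and 10 of 16 by zone, all at 1000 ng/kg/day where dosed. Leaving out each array in turn, genotype in centrilobular captures ranged from 1 to 3 genes, WT centrilobular captures at 3 ng/kg/day from 3 to 6 and WT periportal ones from 1 to 2, while the 2 periportal genes at 22 ng/kg/day and the single genes for genotype (periportal), zone by genotype and zone at 3 ng/kg/day did not change in number. Ahr had its highest adjusted p without KO replicate 6 (-0.83, limma adjusted p = 0.281), Ccdc74a without replicate 4 at 3 ng/kg/day (0.33, limma adjusted p = 0.155) and Glrx without replicate 7 (0.64, limma adjusted p = 0.161). The KO counts at 1000 ng/kg/day and over all doses stayed at 0 under every alternative but set A alone. Signals near the top of the range limit the comparison of Cyp1a1 between zones from 100 ng/kg/day on.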

Other observations

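The sets, the animals that stood apart and the genes that mark them were chosen after the values were seen, while the splits of the animals and the relation of Ahr to Cyp1a1 were planned before their results.

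Further gene lists responded differently between the zones of WT animals at 1000 ng/kg/day. Genes of serine, one-carbon and amino acid metabolism fell more, or rose less, in centrilobular captures for 6 of 14, with Cbs at -1.96 ± 0.14, and the other way for 1, Phgdh at 1.26 ± 0.16 (SE, n = 8 per group; 7 adjusted over the list alone; camera adjusted p = 0.000595, adjusted p = 0.0435 with an estimated correlation). CAR and PXR targets did so for 5 of 11, such as the glucuronosyltransferase Ugt2b1 at -1.39 ± 0.16, and the other way for 1, the P450 Cyp3a2 at 1.15 ± 0.26 (7 adjusted over the list alone; camera adjusted p = 6.72e-05, adjusted p = 0.000942 with an estimated correlation). Glycolysis genes did so for 3 of 11 and the other way for 1, with Gckr at -0.94 ± 0.08 (4 adjusted over the list alone; camera adjusted p = 0.000553, adjusted p = 0.0133 with an estimated correlation). Gluconeogenesis genes did so for 6 of 13 and the other way for 1 (8 adjusted over the list alone; camera adjusted p = 1.59e-05, adjusted p = 0.0435 with an estimated correlation). Periportal hepatocyte markers did so for 8 of 20 and the other way for 3, with G6pc1, the last step of glucose release, at -2.08 ± 0.26 (11 adjusted over the list alone; camera adjusted p = 0.00113, adjusted p = 0.268 with an estimated correlation). Fatty acid synthesis genes did so for 6 of 16, with the desaturase Fads1 at -1.04 ± 0.11 (7 adjusted over the list alone; camera adjusted p = 5.31e-05, adjusted p = 0.0873 with an estimated correlation). Macrophage markers went the other way for 1 of 11, the growth factor receptor Csf1r at 0.95 ± 0.17 (camera adjusted p = 0.0444, adjusted p = 0.424 with an estimated correlation), and lymphocyte markers for 1 of 8, the T cell surface gene Cd2 at 0.54 ± 0.15 (camera adjusted p = 0.0444, adjusted p = 0.0789 with an estimated correlation), each also 1 adjusted over the list alone. Of the 16 lists called by zone all passed again with set as a block, and 15 and 11 within sets A and B.

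Undosed KO animals had lists shifted against WT animals with 0 members called by limma, also adjusted over the list alone except where given. In centrilobular captures fatty acid synthesis genes were lower (camera adjusted p = 0.00107, adjusted p = 0.49 with an estimated correlation; Elovl6, a fatty acid elongase, at -1.22 ± 0.46, limma adjusted p = 0.594). Cell cycle genes were higher (camera adjusted p = 0.000371, adjusted p = 0.144 with an estimated correlation; 1 adjusted over the list alone), with Nusap1, a spindle protein, at 0.56 ± 0.16. Of the 8 lists called in these captures 4 and 6 passed within sets A and B. Growth hormone and sex-biased genes were higher too (camera adjusted p = 0.0453, adjusted p = 0.144 with an estimated correlation), with Cyp2c13 at 1.93 ± 0.75 (SE, n = 8 per group). That change rested largely on KO replicates 4 and 7, at 9.57 and 11.95, and was 0.64 ± 0.27 without the animals that stood apart. The list passed in neither set alone (camera adjusted p = 0.106 and 0.225). Pericentral markers (camera adjusted p = 0.0133) and p53 targets (camera adjusted p = 0.0303) were lower, both with adjusted p = 0.144 with an estimated correlation. In periportal captures lymphocyte markers were lower (camera adjusted p = 0.00928, adjusted p = 0.0871 with an estimated correlation), with Nkg7, a gene of natural killer cells, at -0.39 ± 0.15. Of the 6 lists called there 4 and 2 passed within the sets, and cholesterol synthesis and the unfolded protein response had medians of opposite sign in the sets (-0.181 and 0.072, and -0.048 and 0.254, for sets A and B).

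The 7 KO animals with high Cyp2c13 also had low A1bg, a female-type gene in rat liver, at 3.99 to 7.08 on their arrays, against 7.57 to 12.23 on the other KO arrays. Cyp2c12, another female-type gene, was at 9.40 to 12.42 on them and at 12.33 to 12.79 on the other KO arrays. Further male-type genes varied among these animals, with Cyp2c11 at 5.25 to 11.88 (other KO arrays at most 7.86), Hsd3b5 at 4.53 to 10.66 (at most 4.89), Sult1e1 at 3.55 to 11.78 (at most 4.21) and Cyp2a2 at 5.15 to 12.07 (at most 9.51). In undosed KO replicate 4 Hsd3b5 (4.53 and 5.18), Sult1e1 (3.56 and 3.55) and Cyp2c12 (12.42 and 12.30, centrilobular and periportal) lay in or near the range of the other KO arrays, so a male-type pattern did not hold across all 7. A different pair of animals, KO replicate 3 at 3 ng/kg/day and WT replicate 4 at 1000 ng/kg/day, had Xist at 4.63 to 5.61, with Eif2s3y at most 2.44 and Cyp2c12 at least 11.86. Without these 9 animals the counts were 1309 for the zones in KO animals, 3411 and 1505 for WT centrilobular and periportal captures at 1000 ng/kg/day, 1750 and 645 for the response by genotype and 1118 by zone.

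Between sets A and B 8937 genes differed in centrilobular and 9438 in periportal captures, 98 and 143 of them at least 2-fold. Rnpc3 was higher in set B by 1.75 and 1.90, and the set B minus set A difference was -1.67 and -1.97 for Ddi2 and -1.25 and -1.64 for Rxra, in centrilobular and periportal captures. What differed between the sets was not tested.

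A lower level of the receptor's transcript was tried as a hypothesis for the low Cyp1a1 of some WT periportal captures at 3 ng/kg/day. Over the 8 animals Pearson's r of Ahr and Cyp1a1 was 0.27 (exact permutation p = 0.553) and Spearman's rho 0.07 (exact permutation p = 0.882), r was 0.37 without the 2 animals farthest from the median of Ahr and 0.39 over the 5 animals of set A, and set B held too few. The hypothesis was not borne out, but 8 animals cannot tell a moderate relation from none, so it stays open.

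Each count of called genes was set against other splits of the same animals, 100 with the real one, and the number with as many genes includes the real one. No other split called as many genes (1 in each) for the zones in WT (2141 genes, highest other 1336) and KO animals (1747, highest other 1022). Nor did any for WT centrilobular captures at 100 (574, highest other 347), 300 (1403, 596) and 1000 ng/kg/day (3381, 2681). The same held for WT periportal captures at 100 (56, highest other 7), 300 (451, 60) and 1000 ng/kg/day (1587, 904), for the response by genotype (2022, highest other 1125, and 786, 494), and by zone at 22 (43, 13), 100 (257, 89), 300 (454, 86) and 1000 ng/kg/day (1160, 556). A share of 1 in 100 is the smallest that 100 splits can give, so over 26 comparisons it does not by itself exclude chance. Few splits reached the real count for genotype in centrilobular captures (3 splits with 2 or more genes, highest other 9). The same was seen for WT centrilobular captures at 3 (2 splits with 5 or more, highest other 6) and 22 ng/kg/day (2 splits with 70 or more, highest other 81). With 26 comparisons and another split above the real one in each of these, such numbers do not exclude chance. Chance was not excluded for the number of genes, 1 in each, for genotype in periportal captures (5 splits, highest other 1), the zone difference by genotype (5 splits, highest other 2), WT periportal captures at 3 ng/kg/day (14 splits, highest other 342) and the response by zone at 3 ng/kg/day (17 splits, highest other 23). Nor was it for the count of 2 genes in WT periportal captures at 22 ng/kg/day: 4 splits gave 2 or more (highest other 111), but 5 did among the splits that part the pairs given below. Any split that calls 1 or 2 genes matches such counts, so the splits do not weigh the named genes themselves. Periportal Cyp1a1 was at least 9.68 on every WT array at 22 ng/kg/day and at most 5.24 on undosed WT arrays. With 0 genes called in KO animals all 100 splits gave as many, with highest others of 107 and 2 at 1000 ng/kg/day and 45 and 17 over all doses (centrilobular, periportal).

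Splits with several times the real count point to a structure of the samples. Those with 342 and 111 genes (WT periportal, 3 and 22 ng/kg/day) put all 6 animals of set B on one side, and so did the split with 81 (WT centrilobular, 22 ng/kg/day), not far above the real 70. With the set as a block these comparisons called 1, 2 and 110 genes, and 1, 1 and 31 in set A and 0, 1 and 17 in set B (limma; 458 at an unadjusted p under 0.05 for the 0). The split with 23 genes by zone at 3 ng/kg/day and the one with 107 genes in KO animals put 3 and 5 of 6 on one side. The one with 9 genes for genotype in centrilobular captures put 5 of 6 there, and that comparison called 2 genes with the set as a block and 1 in each set alone. Where samples of equal replicate number all correlated above the bound given with the processing, the real split was also set among 100 splits that part all 8 pairs. This test was added after the splits were seen, and such splits also keep the sets balanced between the sides. For WT centrilobular captures at 3 and 22 ng/kg/day and periportal ones at 100 the real count was then the highest (others at most 2, 21 and 18), while for periportal ones at 22 ng/kg/day 5 of 100 splits gave 2 or more genes, at most 3.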
